A study of Rattus norvegicus with 6 samples.

How the data were processed

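Single-nucleus RNA-seq was measured in the shell of the nucleus accumbens, a ventral striatal region tied to reward and motivation, in adult Long-Evans rats. There were 6 libraries, 3 from males and 3 from females, and each library was a pool of tissue from 4 animals of 1 sex, 24 animals aged 90 to 100 days in all. Per the labels, frozen brain was sliced at 200 µm, the shell was punched, and nuclei were barcoded with the 10x Genomics 3' kit, version 3.1, with 11 cycles of cDNA amplification. Per the file headers, the deposited matrices hold whole UMI counts per gene and nucleus barcode from Cell Ranger 4.0.0, with no normalization. The submitters' processing notes name Cell Ranger and the rat genome build rn6, and the annotation release is not given in the sources used here. Each matrix listed the same 32883 features. The replicates are pools, so the p-values of single genes and of shares below measure the spread between pools of 4 animals and not the spread between animals. Those of gene lists by camera rest on the spread over genes as well.

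The wording of the labels split the libraries into label set A (male pool 1 and female pool 3) and label set B (male pools 2 and 3 and female pools 1 and 2), a split balanced over sex. The values followed this split: the Pearson correlation of log2 CPM (UMIs of a gene scaled to a common library total) was 0.994 between the set A libraries, 0.975 to 0.989 among the set B libraries and 0.944 to 0.970 across the sets. What the label sets stand for is not given in the sources used here. The label set was therefore a term of each fit of sex, and values within each set are printed beside many of those results. The interaction and D1 against D2 fits had library as a block instead. A class difference that varies with the label set was not adjusted for there, and no values within the sets are printed. Replicate numbers were also tried as a block. Across 16970 genes the correlation of deviations between libraries of the same number was -0.756, 0.224 and -0.642 for numbers 1 to 3, and the numbers were not used as pairs. Numbers 1 and 3 each join a set A with a set B library, and the deviations were not corrected for label set. Their values follow the sets and cannot test the pairing. Within set B, number 2 had 0.224, against 0.344 to 0.682 for male and female libraries of unlike number. Between same-sex libraries the chi-square per degree of freedom was at least 25.0, so no 2 libraries were copies of each other.

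The matrices held 41974 barcodes with 238905895 UMIs, and every barcode had at least 500 UMIs. Nuclei were kept with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs. The share of barcodes over the mitochondrial limit was 17.4% and 40.7% in female pools 1 and 2, 13.1% and 23.9% in male pools 2 and 3, and 1.55% and 2.28% in female pool 3 and male pool 1. Doublets were scored with Scrublet as held in scanpy, per library. Its own thresholds marked 0.00597% to 2.37% of nuclei, so the share expected from loading (0.8% per 1000 nuclei) was removed instead, from 2.86% in male pool 2 to 13.4% in female pool 3. After this 34120 nuclei with 186418284 UMIs remained. The kept UMIs per library were 17800039, 10461593 and 76880536 in female pools 1 to 3 and 55993653, 14304665 and 10977798 in male pools 1 to 3, from 3058, 2748, 14256, 8150, 3000 and 2908 nuclei. The 95% Wilson intervals behind each share of nuclei, and the upper limit that a count of 0 allows (3 nuclei), cover counting error only.

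Counts per nucleus were scaled to 10000, log transformed, scaled within each library and clipped at 10. The 3000 most variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 gave 36 clusters. Sex-linked genes, mitochondrial genes and the preset signalling genes (188 genes) were kept out of the clustering, so that they did not set the clusters. Clusters were named from marker lists written beforehand, as "-like", when at least 3 markers were detected and higher than in the other nuclei. That named 19 clusters in 16 classes with 21768 nuclei (63.8%). A further 10 clusters with 9428 nuclei (27.6%) are called by number, and 7 clusters with markers of more than 1 class (2924 nuclei, 8.57%) are called mixed. The leading genes of a cluster describe it and are not results. Shares were compared for 27 classes and unnamed clusters. Counts were summed per library and class for 14 classes with at least 20 nuclei in each library, and over all nuclei, which made 15 fits. Among these were oligodendrocyte precursor-like nuclei (OPC-like) and several classes of medium spiny neurons (MSN), the projection neurons of the striatum. MSN are split into D1 and D2 types by their dopamine receptor. The mixed clusters, joined as a group, cluster 3 and cluster 10 also reached 20 nuclei in each library, with lowest counts of 73, 31 and 40. They were left out of the fits by class, which the limit of 20 nuclei does not account for.

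Sex was tested in each fit with the edgeR quasi-likelihood test on the summed counts, with TMM scaling, filterByExpr and label set as a term, and with Benjamini-Hochberg adjustment within the fit at 0.05. The 15 fits share the same 6 libraries, and all nuclei include those of the classes. A count of fits below is therefore not a count of independent results. A log2 fold change is female minus male. Its standard error (SE) was derived from the fold change and the F statistic of the same test, so it is approximate. Values given with SD are CPM of the 3 pools of a sex. Set A and set B differences are differences of mean log2 CPM (prior count 2) within a label set, with 1 pool per sex in set A and 2 per sex in set B. Whether the sex effect differs between classes was tested with the interaction in edgeR, library as a block, for 3 pairs of classes. D1 MSN-like and D2 MSN-like nuclei were compared in the same way over all genes, and only the preset signalling genes, which had no part in the clustering, are reported. Shares were compared with an exact 2-sided permutation test, for which 3 against 3 libraries cannot give p under 0.1.

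Preset gene lists were tested with limma camera on log2 CPM with a preset correlation of 0.01, for lists with at least 5 members tested. The p-values were Benjamini-Hochberg adjusted over all lists and fits. The test compares the genes of a list with the other genes. Its p-values depend on the spread over genes and on the preset correlation, and do not measure the spread between pools alone. The 24 lists were Y-linked genes, X-linked genes that escape inactivation, sex steroid signalling, glucocorticoid and stress signalling, serotonin receptors, glutamate receptors, GABA synthesis and receptors, acetylcholine, cannabinoid and peptide receptors, dopamine signalling, opioid and striatal neuropeptides, immediate early genes, psychiatric genetics candidates, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, heat shock and chaperones, cholesterol synthesis, myelin, interferon and MHC, dorsal striatal, ventral striatal, and septal and pallidal regional genes, choroid plexus and erythrocyte genes. The lists were written from general knowledge. Of 32883 features, 17543 had a symbol found in the reference gene table, which gives no chromosomes, so no list of all X-linked genes was made.

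The comparisons, lists, markers and naming rule, and 31 alternatives, were fixed before the data were examined. In all nuclei and in the 5 tested classes with most nuclei the rule took up to 12 genes each way by size of change, and up to 4 each way in other classes. A gene had to pass, have a gene symbol, a mean of at least 10 counts per library and sexes that did not overlap. Where under 5 genes passed in this way, the 5 with the smallest p are given as values that did not pass. Sex-linked list members with at least 10 counts, and members of other lists that passed, are named as well. Up to 12 signalling genes each way are named for D1 against D2, and up to 6 per pair for the interaction. Cpa6 and the features LOC680227, AABR07039356.2, AC239701.4 and AC241873.1 fall outside this rule and were chosen after their values were seen, as were the hormone receptor genes whose levels per class are given at the close.

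The alternatives were sex as the only term, replicate number as a block, DESeq2, RLE scaling, no filter on low counts, doublets kept, at least 1000 UMIs per nucleus, equal numbers of nuclei per library, scaling over all libraries before clustering, and leaving out each library in turn. For shares they were other denominators, and for lists an estimated correlation and fry. A mitochondrial limit of 20%, label set B alone, and all nuclei without mixed clusters and clusters 3 and 10 were added after the data were seen. In data simulated at these depths the sex test recovered from 35% (committed oligodendrocyte precursor-like) to 74% (eccentric MSN-like) of genes changed by log2 1 and from 76% to 96% of genes changed by log2 2, with 4 to 17 false calls per class. With nothing changed it made 0 to 2 calls per class. A list raised by log2 0.5 was called in 15 of 15 fits, with 0 false calls among 220 other list tests. Genes were drawn independently in this simulation. It therefore cannot show how often camera calls a list whose genes move together for reasons other than sex.

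Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Samples of the nucleus accumbens core, which the labels mention, and a combined matrix named in the set A labels were not analysed here. Results for a few single genes are not reported here.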

Results

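The nucleus accumbens shell of 3 male and 3 female pools of rats gave 34120 nuclei, of which 63.8% fell in named classes. D1 MSN-like nuclei, which express the dopamine receptor Drd1 and the peptide gene Pdyn in the direct pathway, made up 14.9% (5080 nuclei). The D1 class joined clusters 2 and 4, and female pool 2 had 91.7% of its D1 nuclei in cluster 4 against 19% to 30.8% in the other libraries, a difference that the D1 results below carry. D2 MSN-like nuclei, marked by Drd2, Adora2a and Penk, made up 10.0% (3416). Smaller classes were eccentric MSN-like (1597 nuclei) and Drd3 MSN-like (1196). The latter was named from Drd3, Rreb1 and Foxp2 alone, with 0 of its markers among its 10 leading genes, and its Pde10a level (409 CPM) was near that of OPC-like nuclei (405 CPM) and far below D1 MSN-like cluster 2 (3470 CPM), so its identity as an MSN is uncertain. Oligodendrocyte-like (3303), astrocyte-like (2472), OPC-like (888), microglia-like (444) and committed oligodendrocyte precursor-like nuclei (292), the stage between precursor and myelinating cell, were the main glia. Sst/Npy (409) and Pvalb/Pthlh (290) interneuron-like and cholinergic-like nuclei (243) were rarer. Among unnamed clusters, cluster 8 was led by Chst9 and Grm8, cluster 9 by Reln and Trpc4, cluster 12 by Sema3c and Lhx8, and cluster 19 by Nts, Nr4a3 and Homer1. Glutamatergic-like nuclei (1802) came nearly all from label set A, with a mean share of 7.28% there and 0.0268% in set B. Cluster 3 held 2247 nuclei, of which 1730 came from male pool 1.

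No class share passed a test between males and females, and several differed widely between single pools. Cluster 3 had 1.80% in females and 8.78% in males, with 21.2% in male pool 1 (exact permutation p = 0.3). D1 MSN-like nuclei were 20.5% ± 12.7 of kept nuclei in females and 17.1% ± 4.39 in males (SD, n = 3 pools each, exact permutation p = 0.9), with a female minus male difference of -2.05 points in set A and 6.20 in set B. D2 MSN-like nuclei were 12.8% ± 6.0 and 11.5% ± 3.03, and astrocyte-like nuclei 7.83% ± 1.29 and 8.25% ± 2.48 (exact permutation p = 0.9 and 0.8). Oligodendrocyte-like nuclei were 9.68% ± 7.21 in females, where female pool 2 had 2.69%, and 11.3% ± 3.48 in males (exact permutation p = 0.7). Drd3 MSN-like nuclei alone did not overlap between the sexes, at 2.98% ± 0.366 in females and 4.56% ± 0.843 in males (exact permutation p = 0.1, adjusted p = 1), with differences of -0.837 in set A and -1.95 in set B. By the exact 2-sided permutation test, 0 of 27 classes passed at an adjusted or unadjusted 0.05. The smallest p that 3 against 3 pools can give is 0.1, and 1 class reached it, where chance gives 10%.

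**Figure D1:**
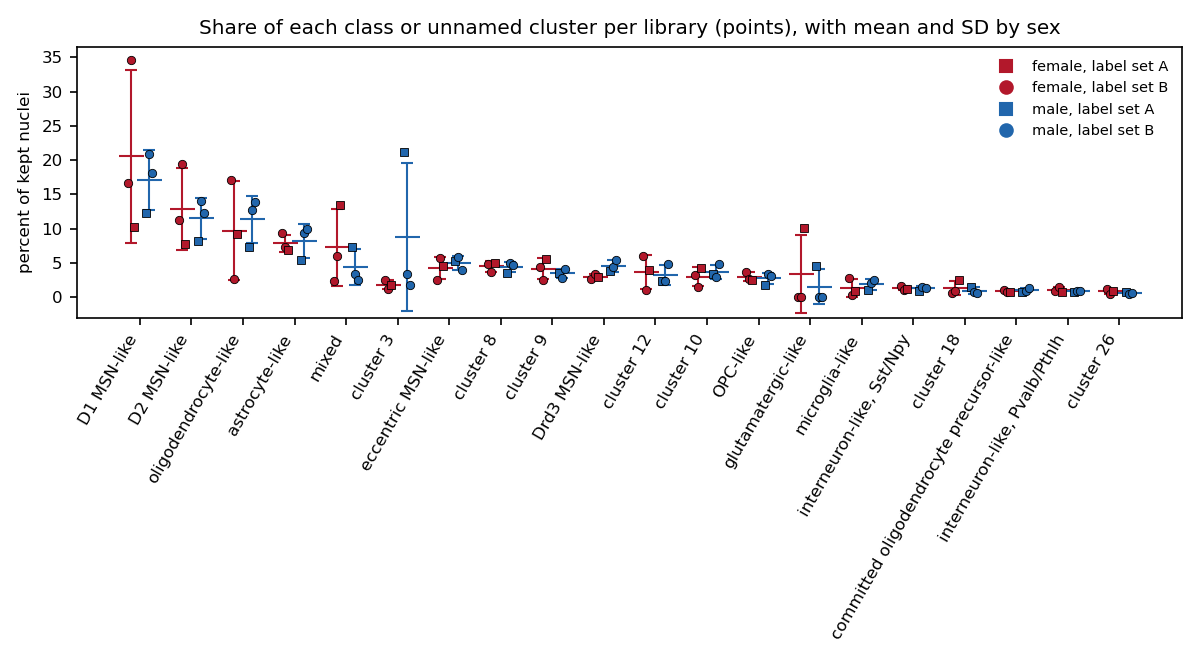
Share of kept nuclei (percent, vertical axis) in each library for 20 classes and unnamed clusters. Points are pools (square, label set A; circle, label set B), and bars are the mean and SD of the 3 female (red) and 3 male (blue) pools; Drd3 MSN-like nuclei had means of 2.98% and 4.56%.

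Y-linked genes carried the clearest difference between the sexes. Summed over all nuclei, Kdm5d, a histone demethylase gene, stood at 103 ± 3.92 CPM in males and 1.83 ± 0.685 in females (SD, n = 3), a log2 fold change of -5.86 (SE 0.26, adjusted p = 9.05e-06, edgeR), with -6.39 in set A and -5.46 in set B. Eif2s3y, which encodes a translation initiation factor subunit, stood at 64.6 ± 6.62 and 0.225 ± 0.0592 CPM (log2 fold change -8.05, SE 0.23, adjusted p = 5.32e-07; -7.60 and -7.83 within the sets). A feature that the files name Ddx3 behaved in the same way, with 77.0 ± 4.64 CPM in males and 0.634 ± 0.245 in females (-7.11, SE 0.28, adjusted p = 5.7e-06; -7.53 and -6.43 within the sets), while the feature named Ddx3y was listed at 0 in every library. Sry was listed at 0 in each female pool and had 29, 59 and 22 counts in male pools 1 to 3. Usp9y did not separate the sexes, at 7.63 ± 3.54 CPM in males and 4.51 ± 2.10 in females (adjusted p = 0.632), and whether it shares reads with its X-linked copy Usp9x was not tested, so this value is uncertain.

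Only features with a wide gap between the sexes passed in all nuclei. Besides these 3 genes, 4 features without an informative gene symbol, chosen after their values were seen, passed in the edgeR test. These 4 features and Ddx3 are counted as sex-limited because of their values in these same data. That the calls of a fit are all sex-limited therefore follows in part from how the set was made. LOC680227 stood at 1817 ± 1773 CPM in females (3770, 1374 and 308 in female pools 1 to 3) and 3.77 ± 0.454 in males (adjusted p = 0.00242; log2 differences of 6.42 and 9.27 in sets A and B). AABR07039356.2 stood at 348 ± 87.8 and 0.828 ± 1.02 CPM (adjusted p = 0.000116; 7.53 and 10.12). AC239701.4 and AC241873.1 were higher in males, at 41.1 ± 5.45 against 0.694 ± 0.468 CPM and 193 ± 15.5 against 9.48 ± 4.19 (adjusted p = 0.00061 and 0.000408; -7.39 and -5.23, and -5.42 and -3.87, within the sets). Without male pool 3 these 4 features missed the threshold (adjusted p = 0.456, 0.0530, 0.0584 and 0.0530), and LOC680227 also did so without male pool 2 (0.132). The count was 7 of 16182 genes in edgeR (2 higher in females, 5 higher in males; 1201 at an unadjusted p under 0.05, where chance gives 809) and 14 in DESeq2. It moved to 16 without female pool 1, 11 without female pool 2 and 3 without male pool 3.

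**Figure D2:**
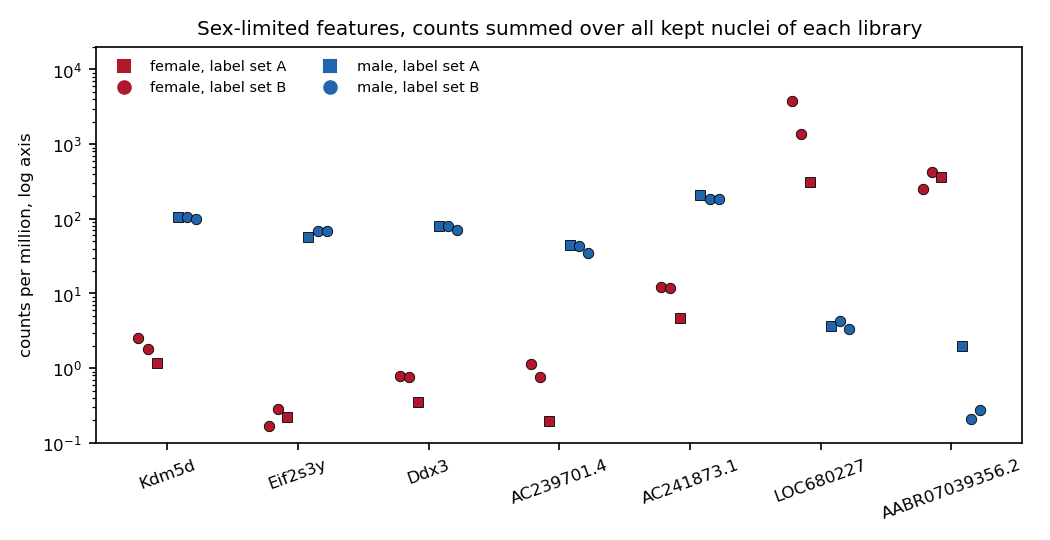
CPM on a log axis for 7 sex-limited features, summed over all kept nuclei of each library (points; red, female; blue, male; square, label set A; circle, label set B). Kdm5d had means of 103 in males and 1.83 in females, and AABR07039356.2 of 348 in females and 0.828 in males.

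X-linked genes that escape inactivation leaned higher in females without passing one by one. Kdm6a, a histone demethylase gene, stood at 281 ± 34.4 CPM in females and 215 ± 23.1 in males in all nuclei (log2 fold change 0.44, SE 0.14, edgeR adjusted p = 0.632; 0.49 and 0.43 within the sets). Its log2 fold change was above 0 in 15 of 15 fits, all of the same pools. It ran from 0.19 in eccentric MSN-like to 0.67 in astrocyte-like nuclei (311 ± 58.4 against 194 ± 35.7 CPM). Eif2s3 gave 0.43 (SE 0.16), Kdm5c 0.37 (SE 0.15), Ddx3x 0.27, Usp9x 0.13 and Pbdc1 0.02 in all nuclei. As a list, these genes were higher in females in 8 of 12 fits (camera; 0 with an estimated correlation), with a median log2 fold change of 0.32 in all nuclei (6 genes, adjusted p = 0.00804) and 0.37 in astrocyte-like nuclei (5 genes, adjusted p = 0.00544). Adjusted over the list alone, Kdm6a passed in astrocyte-like, OPC-like and cluster 9 nuclei, and Eif2s3 in astrocyte-like nuclei. The fits called fell to 2 without female pool 1, 1 without female pool 3, 2 without male pool 1 and 5 without male pool 3.

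Besides the 7 features above, no gene passed in all nuclei, although several had small p-values. The mitochondrial gene Mt-nd6 stood at 36.1 ± 26.1 CPM in females and 76.0 ± 59.1 in males (log2 fold change -0.97, SE 0.16, adjusted p = 0.332; -0.92 and -0.99 within the sets), and Mt-nd6 in all nuclei passed in DESeq2 (0.00116) and without female pool 1 (0.0381). Rbm3, a cold-inducible RNA-binding protein gene, stood at 62.1 ± 13.8 and 104 ± 15.8 CPM (-0.69, SE 0.13). Zbtb16, a transcription factor gene induced by glucocorticoids, stood at 42.3 ± 3.76 and 22.7 ± 4.65 CPM (0.96, SE 0.18; 0.49 and 1.21 within the sets), and Zbtb16 in all nuclei passed in DESeq2 (0.00202). Nr4a3, an immediate early gene, stood at 74.9 ± 44.6 and 35.2 ± 42.3 CPM (1.68, SE 0.35; 0.62 and 2.26), and Nr4a3 in all nuclei passed in DESeq2 (0.000716) and without female pool 1 (0.0127). Cnih3, an AMPA receptor auxiliary subunit gene, gave 0.73 (SE 0.16). The last 4 genes had an adjusted p of 0.632 in edgeR, and for Mt-nd6, Zbtb16 and Nr4a3 the alternatives reached 1.0.

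Within D1 MSN-like nuclei, which in female pool 2 came mostly from another cluster, sex-limited features again made up every call. Kdm5d stood at 105 ± 5.38 CPM in males and 1.40 ± 0.474 in females, and Eif2s3y at 59.5 ± 3.61 and 0.0400 ± 0.0693. Nearest among other genes was Spata16, at 51.1 ± 29.1 CPM in females and 83.5 ± 46.2 in males (log2 fold change -0.70, SE 0.13, adjusted p = 0.381; -0.77 and -0.66 within the sets). The thyrotropin receptor gene Tshr gave -0.83 (SE 0.17) and Asb4 -0.89 (SE 0.19), while the acid-sensing channel gene Asic2 stood at 175 ± 28.8 CPM in females and 113 ± 8.50 in males (0.66, SE 0.14, adjusted p = 0.699). In edgeR 7 of 12677 genes passed, with 880 at an unadjusted p under 0.05, where chance gives 634, and 9 in DESeq2. In D2 MSN-like nuclei 8 of 11603 passed (721 unadjusted, where chance gives 580, and 9 in DESeq2). The gene beyond the sex-limited ones was Cpa6, a carboxypeptidase gene chosen after its values were seen. It stood at 24.3 ± 14.9 CPM in females and 57.8 ± 34 in males (-1.21, SE 0.18, adjusted p = 0.0427; -1.15 and -1.23 within the sets). Cpa6 in D2 MSN-like nuclei missed the threshold in 13 of 17 other settings, among them without female pools 2 and 3 (adjusted p = 0.0720 and 0.285) and without male pools 1 to 3 (0.298, 0.366 and 0.561). Its adjusted p ran from 1.43e-05 to 1.0 over all alternatives. Cntnap4, a neurexin-family gene, stood at 25.3 ± 7.41 and 12.5 ± 3.34 CPM there (1.04, SE 0.23, adjusted p = 0.753).

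Astrocyte-like, OPC-like, eccentric MSN-like, Drd3 MSN-like, cluster 12 and both interneuron-like classes also had calls for sex-limited features alone. In astrocyte-like nuclei Prr4 had the smallest p among other genes, at 38.6 ± 19.8 CPM in females and 105 ± 69.7 in males (log2 fold change -1.28, SE 0.25, adjusted p = 0.0971), followed by Sat1, of polyamine breakdown, at 1062 ± 317 and 2122 ± 955 (-0.94, SE 0.20, adjusted p = 0.240). In eccentric MSN-like nuclei the synaptic scaffold gene Homer1 stood at 1034 ± 276 and 543 ± 221 CPM (0.98, SE 0.23, adjusted p = 0.486; 0.36 and 1.30 within the sets). Opcml, a cell adhesion gene, gave 1.38 (SE 0.30, adjusted p = 0.120) in Drd3 MSN-like nuclei, and the neurofilament gene Nefh -0.93 (SE 0.22, adjusted p = 0.626) in cluster 12. In Sst/Npy interneuron-like nuclei Cadps2 gave 1.65 (SE 0.37, adjusted p = 0.113). The edgeR counts were 6 in astrocyte-like, 6 in OPC-like, 7 in eccentric MSN-like, 7 in Drd3 MSN-like, 7 in cluster 12, 7 in Sst/Npy and 4 in Pvalb/Pthlh nuclei, with 436, 278, 393, 302, 649, 251 and 173 genes at an unadjusted p under 0.05 and 7, 6, 8, 7, 7, 7 and 4 called in DESeq2. At an unadjusted 0.05 chance gives 442, 294, 448, 335, 543, 279 and 198 in the same order, so only cluster 12 lay above it. The astrocyte-like count rose to 26 without female pool 1. The Drd3 MSN-like count rose to 15 without female pool 2 and 11 without male pool 2, and that of cluster 12 to 11 without female pool 3. Sst/Npy gave 17 without female pool 2 and 3 without male pool 1, and Pvalb/Pthlh 13 without female pool 1 and 2 without male pool 1.

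Kdm5d separated the sexes in these classes, and some calls of sex-limited genes were lost when 1 pool was left out. It stood at 109 ± 21.8 CPM in males and 1.91 ± 0.883 in females in astrocyte-like nuclei, at 107 ± 37.3 and 0.414 ± 0.716 in Sst/Npy nuclei and at 111 ± 51.2 and 6.09 ± 4.79 in Pvalb/Pthlh nuclei. Kdm5d in interneuron-like, Sst/Npy nuclei missed the threshold without male pool 1 (adjusted p = 0.172), and Kdm5d in interneuron-like, Pvalb/Pthlh nuclei without female pool 3, male pool 1 and male pool 3 (0.0787, 0.251 and 0.0533). Kdm5d in committed oligodendrocyte precursor-like nuclei did so without female pool 3, male pool 2 and male pool 3 (0.116, 0.179 and 0.1), and Ddx3 in committed oligodendrocyte precursor-like nuclei without female pool 3 and male pools 1 to 3 (0.116, 0.564, 0.109 and 0.0754). Eif2s3y in interneuron-like, Sst/Npy nuclei was lost without female pool 3 (0.308) and male pool 1 (0.722), and Ddx3 in interneuron-like, Sst/Npy nuclei without male pool 1 (0.258). The unnamed feature AC239701.4 was lost most often. AC239701.4 in oligodendrocyte-like nuclei, AC239701.4 in Drd3 MSN-like nuclei and AC239701.4 in interneuron-like, Sst/Npy nuclei missed the threshold without female pool 3 (0.864, 0.155 and 0.216) and without male pool 1 (0.998, 0.502 and 0.569). AC239701.4 in cluster 19 did so without female pool 3 (0.0579), and AC239701.4 in cluster 9 and AC239701.4 in eccentric MSN-like nuclei without male pool 1 (0.105 and 0.0549). Without male pool 1, AC241873.1 in interneuron-like, Pvalb/Pthlh nuclei had an adjusted p of 0.173.

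Sgk1 was higher in oligodendrocyte-like nuclei of females. This gene encodes a kinase induced by glucocorticoids and by osmotic stress. It stood at 186, 119 and 85.8 CPM in female pools 1 to 3 (130 ± 51.3) and 33.3, 31.4 and 44.2 in male pools 1 to 3 (36.3 ± 6.89), a log2 fold change of 1.81 (SE 0.26, adjusted p = 0.00295, edgeR), with 1.28 in set A and 1.90 in set B. Values that did not pass included Peak1, a kinase-like scaffold gene, at 108 ± 26.6 and 54.2 ± 6.87 CPM (1.05, SE 0.22, adjusted p = 0.159), and the glucocorticoid-responsive factor Klf9, at 148 ± 33.6 and 64.8 ± 18.5 (1.14, SE 0.25, adjusted p = 0.275; 0.46 and 1.49 within the sets). Sgk1 missed the threshold without male pool 2 (log2 fold change 1.60, adjusted p = 0.143) and without male pool 3 (1.84, 0.0657). Over all alternatives the adjusted p of Sgk1 in oligodendrocyte-like nuclei ran from 1.23e-09 to 1. Of 8644 genes 8 passed (414 unadjusted, where chance gives 432, and 8 in DESeq2), and 133 passed without female pool 1.

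In cluster 9, Ebf1 was higher in females. This transcription factor gene of striatal development, also used as a D1 marker, stood at 57.1 ± 14.1 CPM in females and 16 ± 7.11 in males (log2 fold change 1.76, SE 0.30, adjusted p = 0.0152, edgeR; 1.70 and 1.88 within the sets). It missed the threshold without female pool 3 (adjusted p = 0.853), male pool 1 (0.617) and male pool 2 (0.112), and its log2 fold change was 0.05 with at least 1000 UMIs per nucleus. The adjusted p of Ebf1 in cluster 9 ran from 5.76e-06 to 1.0 over the alternatives. In cluster 8 the ribosomal protein gene Rps23 was lower in females, at 75.1 ± 40.9 CPM and 154 ± 99.7 in males (-0.95, SE 0.20, adjusted p = 0.0426; -0.64 and -1.05 within the sets), a call lost in DESeq2 (0.296) and without female pool 1 (0.300), female pool 3 (0.1), male pool 1 (0.0871) and male pool 3 (0.769). Alternatives for Rps23 in cluster 8 gave adjusted p from 0.0127 to 1.0. Each cluster had 8 calls in edgeR, with 373 and 555 genes at an unadjusted p under 0.05 in clusters 9 and 8, where chance gives 458 and 428. The count in cluster 8 rose to 15 without female pool 1 and 13 without female pool 2.

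Cluster 19, MSN nuclei with high immediate early genes, had the most calls between the sexes among the neuron classes tested. Its Drd2 levels were 109 to 426 CPM and its Drd1 levels 7.49 to 28.3. Sik2, a salt-inducible kinase gene of the CREB coactivator pathway, stood at 988 ± 357 CPM in females and 335 ± 101 in males (log2 fold change 1.55, SE 0.26, adjusted p = 0.000912, edgeR), with 0.48 in set A and 2.16 in set B. Ell2, of transcription elongation, stood at 406 ± 33.2 and 156 ± 115 CPM (1.49, SE 0.25, adjusted p = 0.00108; 0.63 and 2.19), and Ubash3b, a tyrosine phosphatase gene, at 185 ± 112 and 46.1 ± 5.47 (1.62, SE 0.31, adjusted p = 0.00592; 0.56 and 2.45). The calcitonin receptor gene Calcr (1.29, SE 0.30, adjusted p = 0.0371; 101 ± 62.0 and 38.3 ± 15.7 CPM) and the BDNF receptor gene Ntrk2 (0.93, SE 0.22, adjusted p = 0.0334; 2370 ± 1012 and 1253 ± 141 CPM) rose as well. Homer1 (1.41), Nr4a3 (1.27), Nts (1.04) and Peli1 passed too, but they are among the genes that lead this cluster, so its make-up and their level cannot be told apart. The same limit reaches the other called genes. The mean of all called genes higher in females ranked the libraries as Homer1 did, from female pool 2 (3617 CPM of Homer1) to male pool 3 (1015 CPM). In edgeR 39 of 6841 genes passed, 33 of them higher in females and 32 not sex-limited. At an unadjusted p under 0.05 lay 508 genes, where chance gives 342, and DESeq2 called 38. The smallest library held 35 nuclei. Counts were 69 without female pool 3, 71 without male pool 1, 22 without male pool 2 and 7 without male pool 3, and without male pool 3 the adjusted p of Sik2, Ell2 and Ubash3b were 0.206, 0.147 and 0.384. Calcr was lost without female pool 1, male pool 2 and male pool 3 (adjusted p = 0.287, 0.361 and 0.412 for Calcr in cluster 19). Ntrk2 in cluster 19 was lost in 10 of 17 other settings, among them without female pool 2, male pool 2 and male pool 3 (adjusted p = 0.278, 0.329 and 0.412). Over all alternatives Sik2 in cluster 19 ran from 2.21e-09 to 0.889.

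In committed oligodendrocyte precursor-like nuclei, Bcl11a, Gria1 and Gabrg3 were among 34 genes higher in females. Bcl11a, a transcription factor gene of neurons, stood at 136 ± 41.9 CPM in females and 5.60 ± 9.70 in males (log2 fold change 3.91, SE 0.59, adjusted p = 0.00609, edgeR; 2.75 and 3.68 within the sets). The AMPA receptor gene Gria1 stood at 244 ± 92.7 and 36.6 ± 7.88 CPM (2.67, SE 0.40, adjusted p = 0.00609; 2.64 and 2.17), and the GABA-A receptor gene Gabrg3 at 921 ± 447 and 142 ± 12.5 (2.61, SE 0.37, adjusted p = 0.0044; 2.65 and 2.33). Caln1 (3.19), Slit2 (2.81), Camk1d (2.70), Grin1 (2.38), Ntrk3 (2.18), Grin2b (2.07), Lrfn5 (1.87), Ntrk2 (1.63), Homer1 (1.51) and Negr1 (1.37) were higher in females as well. General MSN markers, not tested between the sexes in these nuclei, stood at 25.8% ± 22.1 of their D1 MSN-like level in females (8.52%, 50.7% and 18.1% in female pools 1 to 3) and 8.89% ± 1.11 in males. In edgeR 39 of 2844 genes passed, 36 of them higher in females and 34 not sex-limited. At an unadjusted p under 0.05 lay 289 genes, where chance gives 142, and DESeq2 called 44. Libraries held only 21 to 108 of these nuclei. Counts were 174 without female pool 1, 23 without female pool 2, 3 without female pool 3, 3 without male pool 1, 4 without male pool 2 and 3 without male pool 3, and Bcl11a, Gria1 and Gabrg3 missed the threshold without female pool 3 and without each of the 3 male pools.

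**Figure D3:**
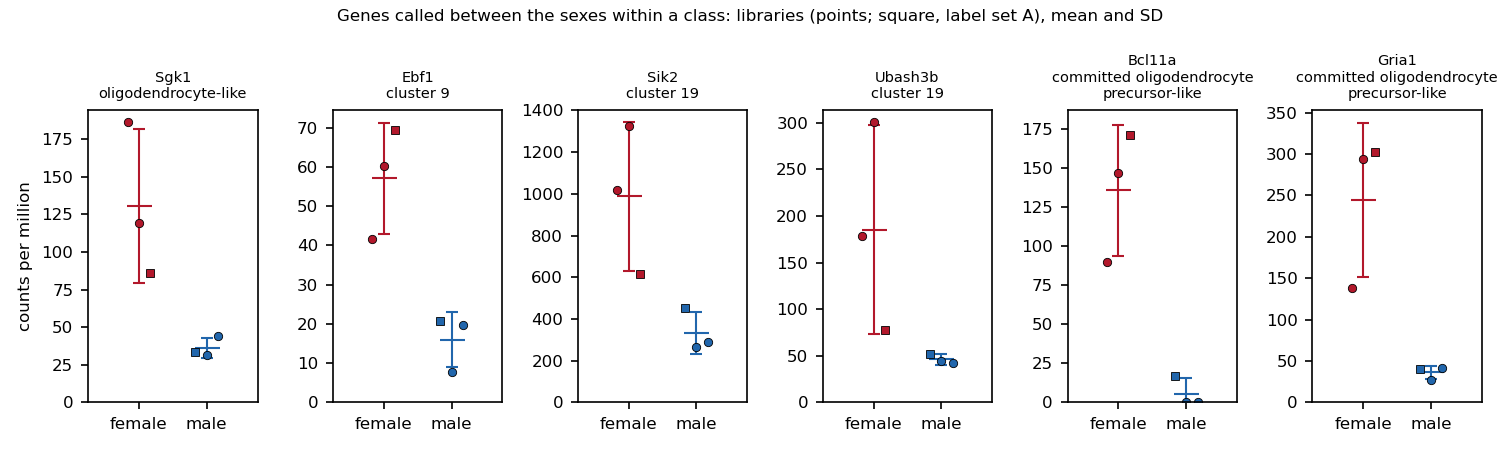
CPM in each library for Sgk1 in oligodendrocyte-like nuclei, Ebf1 in cluster 9, Sik2 and Ubash3b in cluster 19, and Bcl11a and Gria1 in committed oligodendrocyte precursor-like nuclei. Points are pools (square, label set A; circle, label set B), bars are mean and SD by sex, and female means exceed male means in each panel (130 against 36.3 for Sgk1).

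Cytosolic ribosomal protein genes were lower in females in 11 of 15 fits with the preset correlation of camera, and in 0 with an estimated correlation. Their median log2 fold change was -0.40 in all nuclei (35 genes, 0 of them above 0, camera adjusted p = 1.05e-06 with the preset correlation), -0.41 in cluster 8 (adjusted p = 3.98e-08), -0.53 in cluster 12 and -0.49 in Sst/Npy interneuron-like nuclei, and 11 of 15 fits were called with the preset correlation. Adjusted over the list alone, 12 genes passed in cluster 8, among them Rps23 and Rps20. Nuclear genes of oxidative phosphorylation were lower in 9 of 15 fits (0 with an estimated correlation), with a median of -0.27 in all nuclei (36 genes, adjusted p = 0.00118) and -0.43 in cluster 12 (adjusted p = 0.00156), where Cox7c, Ndufa4, Cox6c, Ndufb9, Ndufb3 and Atp5mc1 passed when adjusted over the list alone. In sets A and B the median differences in all nuclei were -0.45 and -0.35 for the ribosomal genes and -0.33 and -0.31 for oxidative phosphorylation. Such short housekeeping transcripts also follow the quality of a nucleus preparation, and median mitochondrial shares of kept nuclei ran from 0.143% in female pool 3 to 2.93% in female pool 2. Fits called for the ribosomal list were 1 without female pool 1 and 3 without male pool 3, and for oxidative phosphorylation 0 without either, while leaving out female pool 2 or male pool 2 gave 15 for both lists. Oxidative phosphorylation gave 3 without female pool 3 or male pool 1.

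Several lists of receptor and activity genes leaned the other way, and others did not. The median was above 0 in 0 of 3 fits for serotonin receptors, 0 of 13 for opioid and striatal neuropeptides and 5 of 15 for dopamine signalling. Glutamate receptor genes were higher in females in 8 of 15 fits, with a median log2 fold change of 0.22 in all nuclei (22 genes, 20 above 0, camera adjusted p = 0.00118), 0.39 in oligodendrocyte-like nuclei and 0.78 in committed oligodendrocyte precursor-like nuclei. With an estimated correlation 0 fits were called for this list and for each other list of this paragraph. Mean MSN marker RNA moved the same way in these glia. In oligodendrocyte-like nuclei it stood at 12.8% ± 11.0 of the D1 MSN-like level in females and 6.18% ± 1.70 in males. Female pools 1 to 3 had 2.52%, 24.3% and 11.5% there, with pool 1 below each male pool. In committed oligodendrocyte precursor-like nuclei it stood at 25.8% ± 22.1 and 8.89% ± 1.11, with 8.52% in female pool 1. Psychiatric genetics candidates, such as Grm5, Tenm4 and Mef2c, were higher in 7 of 15, with a median of 0.19 in all nuclei (44 genes, 37 above 0, adjusted p = 0.000129). Immediate early genes were higher in 5 of 10, most in eccentric MSN-like nuclei (13 genes, median 0.62, adjusted p = 1.05e-06), where Homer1, Nr4a3 and Btg2 passed when adjusted over the list alone, while in D1 MSN-like nuclei their median was -0.09. This activity signal came from set B, since the median difference of the immediate early genes was -0.26 in set A and 0.70 in set B in all nuclei, and -0.04 and 1.64 in eccentric MSN-like nuclei. Glutamate receptor genes gave 0.12 and 0.23 in all nuclei, the psychiatric list 0.10 and 0.24, and myelin genes -0.11 and -0.49. Myelin genes were lower in females in all nuclei (21 genes, median -0.37, adjusted p = 0.00457) and in committed oligodendrocyte precursor-like nuclei (-0.40, adjusted p = 0.00175, with Mog among those passing when adjusted over the list alone). In summed nuclei the myelin list also moves with the share of oligodendrocyte-like nuclei, which differed by 1.87 points in set A and -3.43 in set B. Interferon and MHC genes were lower in all nuclei (-0.24, adjusted p = 0.0245) and in D2 MSN-like nuclei (-0.36, adjusted p = 0.0173). Glutamate receptor fits called were 4 without female pool 1, female pool 3 or male pool 1 and 3 without male pool 3. For the psychiatric list they were 3, 2, 3 and 3 in the same order and 12 without female pool 2 or male pool 2. Immediate early fits fell to 3 without female pool 2, male pool 2 or male pool 3, interferon fits to 0 without female pool 3 and 1 without male pools 1 or 2, and myelin fits from 2 to 1 without female pool 2 or male pool 3.

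Oligodendrocyte-like nuclei had further lists called. Glucocorticoid and stress genes were higher in females (9 genes, median log2 fold change 0.63, camera adjusted p = 0.0114), with Sgk1 and Zbtb16 passing when adjusted over the list alone. With an estimated correlation 0 fits were called for this list or the others of this paragraph. Within the sets the median differences of this list were 0.10 and 0.48. Zbtb16 stood at 143 ± 109 CPM in females and 37.1 ± 22.5 in males, with a difference of 0.02 in set A and 2.56 in set B. The list was not called without female pool 1, male pool 2 or male pool 3 (0 fits each). Cholesterol synthesis genes were lower in females (16 genes, median -0.19, adjusted p = 0.0138, Dhcr7 passing when adjusted over the list alone), in 1 of 13 fits and in 2 without male pool 2. Acetylcholine, cannabinoid and peptide receptor genes (0.43, adjusted p = 0.0089) and GABA genes (0.29, adjusted p = 0.0196) were higher. Mean MSN marker RNA of these nuclei was also higher in females (12.8% ± 11.0 against 6.18% ± 1.70). It was 24.3% in female pool 2, but 2.52% in female pool 1, below each male pool. The acetylcholine, cannabinoid and peptide receptor list was called in 3 of 14 fits, with 0 without female pool 3 and 1 without female pool 1 or male pool 1. The GABA list was called in 1 of 14, with 0 without female pools 2 and 3 and male pools 1 and 2. Dopamine signalling genes were called in 1 of 15 fits, committed oligodendrocyte precursor-like nuclei (0.85, adjusted p = 0.04999). Mean MSN marker RNA moved with them there (25.8% ± 22.1 against 8.89% ± 1.11, with 8.52%, 50.7% and 18.1% in female pools 1 to 3). The dopamine list was called in 0 fits without female pool 3, male pool 1 or male pool 2 and in 2 without female pools 1 or 2.

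Sex steroid signalling genes were not called in any of 14 fits, nor were serotonin receptors (3 fits), opioid and striatal neuropeptides (13), mitochondrially encoded genes (15), heat shock genes (15), dorsal (10) or ventral (6) striatal genes, septal and pallidal genes (1) or erythrocyte genes (1). Fewer than 5 Y-linked and choroid plexus genes were tested in any fit, so these lists had no test. Without female pool 2, 10 fits were called for mitochondrially encoded genes, 4 for opioid and striatal neuropeptides, and 1 each for sex steroid signalling, serotonin receptors, erythrocyte and septal and pallidal genes. Without male pool 3, 1 fit each was called for heat shock, erythrocyte and ventral striatal genes. In all, 59 of 246 list tests passed with the preset correlation, 54 of them with the same sign in both sets, and the 5 others were those of the immediate early genes. With RLE scaling 0 called medians changed sign. With an estimated correlation 0 passed, the lowest adjusted p being 0.850, and 1 passed in fry, which asks whether a list moves on balance in 1 direction: interferon and MHC genes in D1 MSN-like nuclei (median -0.21, adjusted p = 0.0347). The list count was 26 without female pool 1, 95 without female pool 2, 27 without female pool 3, 33 without male pool 1 and 31 without male pool 3.

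**Figure D4:**
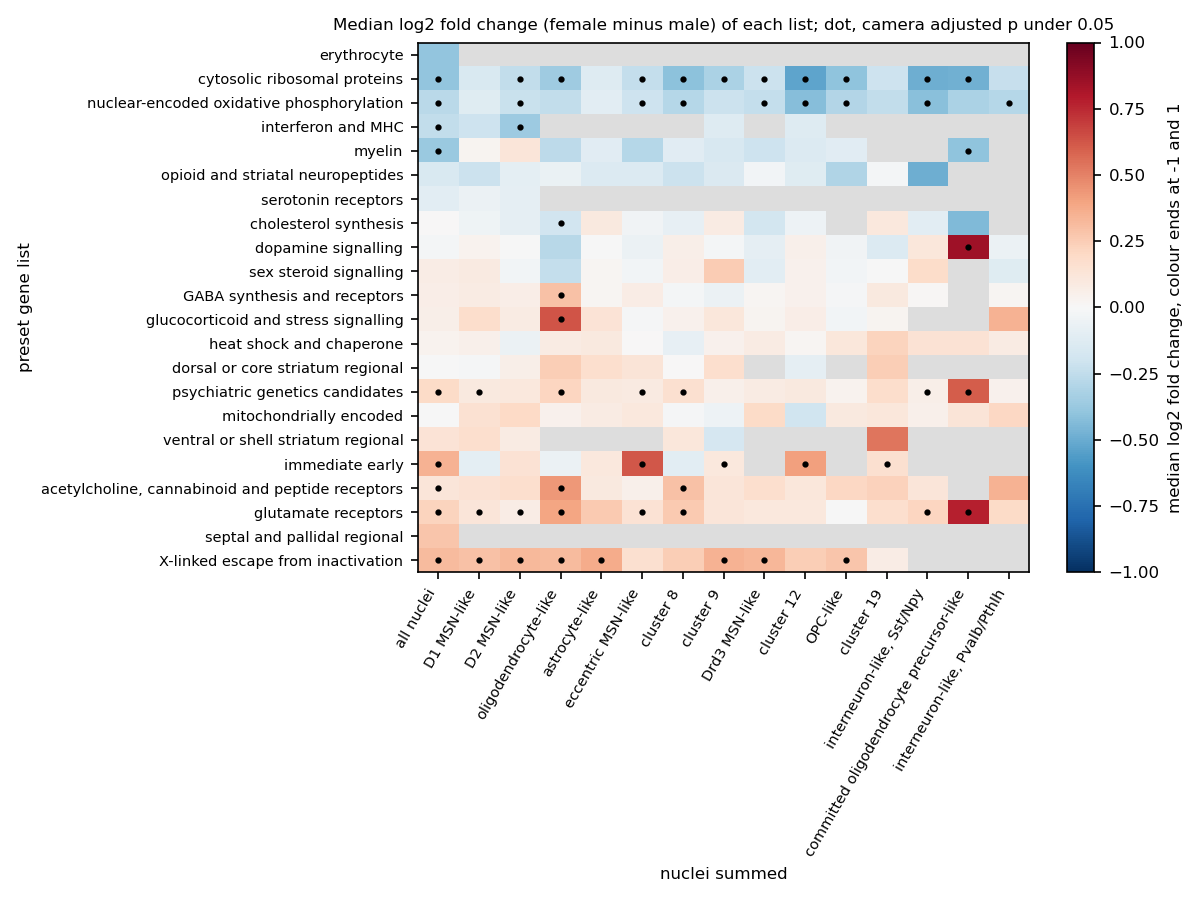
Median log2 fold change (female minus male, colour) of each preset gene list (vertical axis) in each of 15 fits (horizontal axis). Dots mark a camera adjusted p under 0.05 with the preset correlation, grey marks lists not tested, and the ribosomal list in all nuclei has a median of -0.40.

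The sex effect was not shown to differ between cell classes. Sema3e, a semaphorin gene, had the smallest p between D1 and D2 MSN-like nuclei, with sex effects of 0.08 and 0.56 (difference 0.43, SE 0.09, adjusted p = 0.242). Smarca1 gave a difference of 1.52 (SE 0.40) between D1 MSN-like and oligodendrocyte-like nuclei, and Dpysl4 1.04 (SE 0.27) between D1 MSN-like and astrocyte-like nuclei (adjusted p = 1 for both). The edgeR interaction test called 0 of 13267, 0 of 12623 and 0 of 12947 genes in the 3 pairs, and DESeq2 called 0, 0 and 0. At an unadjusted p under 0.05 lay 537, 263 and 287 genes. Each of these counts was below the 0.05 of genes that chance gives, so 0 calls do not show that the sex effects are alike. Without female pool 1, 65 genes were called between D1 MSN-like and oligodendrocyte-like nuclei, 1 without female pool 3, and 2 between D1 and D2 MSN-like nuclei without male pool 1. Sgk1 and Cpa6 are therefore not shown to be specific to their class, and no interaction was fitted for clusters 8, 9 and 19 or committed oligodendrocyte precursor-like nuclei.

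Receptor genes separated D1 from D2 MSN-like nuclei. On the D1 side, the muscarinic receptor gene Chrm4 stood at 66.3 ± 9.37 CPM in D1 and 9.12 ± 1.62 in D2 MSN-like nuclei (SD, n = 6 libraries; log2 fold change 2.84, SE 0.09, adjusted p = 3.33e-27, edgeR). Grin3a, an NMDA receptor subunit gene, stood at 42.9 ± 8.25 and 13.5 ± 2.79 (1.61, SE 0.09, adjusted p = 1.91e-18), and the kappa opioid receptor gene Oprk1 at 28.2 ± 6.53 and 10.7 ± 3.33 (1.31, SE 0.11, adjusted p = 2.46e-13). The progesterone receptor gene Pgr stood at 15 ± 2.37 and 6.03 ± 3.34 (1.07, SE 0.16, adjusted p = 1.09e-06). Sstr4 (1.68), Grik1 (1.24), Npy5r (0.94), Adra2c (0.93), Chrm5 (0.91), Cnr1 (0.78), Grik2 (0.61) and Ntrk3 (0.50) were higher in D1 as well. Adra2c missed the threshold without female pool 2, in DESeq2 and in each sex alone.

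On the D2 side the kainate receptor gene Grik3 stood at 294 ± 50.5 CPM in D2 and 14.9 ± 3.33 in D1 MSN-like nuclei (log2 fold change D1 minus D2 -4.34, SE 0.06, adjusted p = 6.1e-41). The delta opioid receptor gene Oprd1 stood at 192 ± 29.8 and 29.8 ± 6.83 (-2.66, SE 0.06, adjusted p = 1.65e-32), opposite to Oprk1. Htr2c, a serotonin receptor gene, stood at 1634 ± 96.9 and 636 ± 146 (-1.38, SE 0.05, adjusted p = 4.69e-24), and the stress peptide receptor gene Crhr1 at 16.8 ± 3.85 and 6.02 ± 2.38 (-1.46, SE 0.13, adjusted p = 1.1e-11). Esr2, the estrogen receptor beta gene, was higher in D2 at 9.58 ± 1.79 and 4.04 ± 1.25 (-1.17, SE 0.17, adjusted p = 8.3e-07). Calcr (-2.20), Trhr (-0.59), Esrrg (-0.57), Htr2a (-0.49), Gria3 (-0.47), Greb1 (-0.46) and Htr6 (-0.41) were higher in D2 as well. The 24 named genes kept their direction in 6 of 6 libraries.

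Counted by family, 53 of 91 tested signalling genes differed between D1 and D2 MSN-like nuclei, 23 higher in D1 and 30 in D2, and 58 passed when adjusted over the list alone. Glutamate receptors split 5 to D1 and 8 to D2 of 19, GABA genes 4 and 6 of 18, sex steroid genes 2 and 6 of 13, serotonin receptors 1 and 3 of 5, and acetylcholine, cannabinoid and peptide receptors 9 and 4 of 21. Glucocorticoid and stress genes split 0 and 2 of 11, and opioid and striatal neuropeptides 2 and 1 of 4. Over all genes 2047 of 12436 passed, 1105 of them higher in D1. Females alone gave 31 signalling genes, and Npy5r, Greb1 and Htr6 missed the threshold there. Greb1 also missed it in DESeq2 and in males only.

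**Figure D5:**
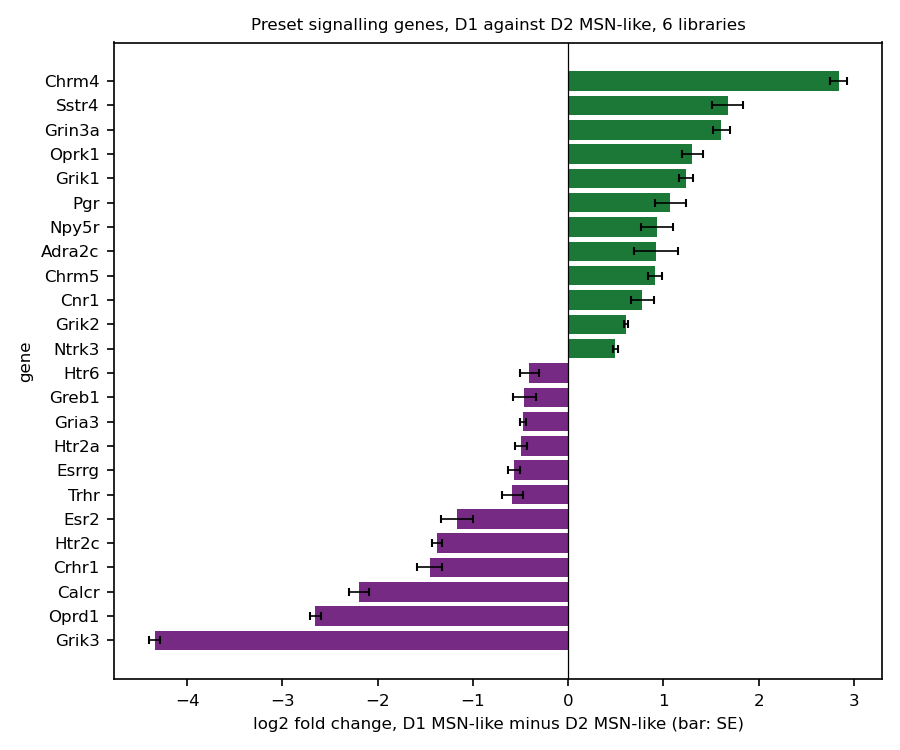
Log2 fold change of D1 minus D2 MSN-like nuclei (horizontal axis) for 24 preset signalling genes (vertical axis), over 6 libraries with library as a block. Bars start at 0 and whiskers are SE; Chrm4 lies at 2.84 and Grik3 at -4.34.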

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

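A mitochondrial limit of 20%, label set B alone, and all nuclei without mixed clusters and clusters 3 and 10 were chosen after seeing results, and the other settings beforehand. Calls of named sex genes were kept in 1708 cases and lost in 307, with 0 changes of direction. These cases pool the sex-limited features of each fit with the other calls, so they do not give the stability of the latter. Sgk1 in oligodendrocyte-like nuclei was lost in 4 of 16 settings and Sik2 in cluster 19 in 4 of 17. Ebf1 in cluster 9 was lost in 9 of 16, Cpa6 in D2 MSN-like nuclei in 13 of 17, and Negr1 in committed oligodendrocyte precursor-like nuclei in 14 of 17. Among genes that did not pass, only Pbdc1 in all nuclei (0.02) changed direction, to -0.0018 without female pool 2, -0.0524 without female pool 3, -0.0526 without male pool 1 and -0.0536 in set B alone, against 0.0889 without male pool 3.

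With replicate number as a block in place of label set, the count of sex genes fell to 3 in all nuclei, 3 in D1 MSN-like, 2 in D2 MSN-like, 2 in oligodendrocyte-like, 5 in cluster 8, 2 in Drd3 MSN-like, 2 in OPC-like, 4 in cluster 19, 2 in Sst/Npy, 0 in committed oligodendrocyte precursor-like and 1 in Pvalb/Pthlh nuclei. Sgk1 in oligodendrocyte-like nuclei and Ebf1 in cluster 9 missed the threshold in this setting. The pairing could be judged only within set B, where it had no support in the values. Numbers 1 and 3 each join libraries of both label sets, so this block does not take up the difference between the sets. The cause of the lower counts was not tested further.

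Leaving out 1 library in turn gave 3 to 16 genes in all nuclei, 7 to 133 in oligodendrocyte-like, 6 to 26 in astrocyte-like, 7 to 15 in cluster 8, 6 to 15 in Drd3 MSN-like, 7 to 11 in cluster 12, 7 to 71 in cluster 19, 3 to 17 in Sst/Npy, 3 to 174 in committed oligodendrocyte precursor-like and 2 to 13 in Pvalb/Pthlh nuclei. List calls ran from 26 to 95. The interaction gave 0 to 2 genes for D1 against D2 MSN-like and 0 to 65 for D1 MSN-like against oligodendrocyte-like nuclei.

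Without a filter on low counts the genes called were 13 in all nuclei, 106 in D1 MSN-like, 57 in D2 MSN-like, 35 in oligodendrocyte-like, 20 in astrocyte-like, 18 in eccentric MSN-like, 13 in cluster 9, 14 in Drd3 MSN-like, 17 in cluster 12, 10 in OPC-like, 83 in cluster 19, 12 in Sst/Npy, 202 in committed oligodendrocyte precursor-like and 7 in Pvalb/Pthlh nuclei. DESeq2 called 14 in all nuclei. Equal numbers of nuclei left 3 in oligodendrocyte-like and 4 in Sst/Npy nuclei and gave 14 in cluster 12. Set B alone left 3 in Sst/Npy and 2 in Pvalb/Pthlh nuclei, and sex as the only term left 2 in Pvalb/Pthlh nuclei.

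In cluster 19, with 39 genes, the count was 6 with sex as the only term, 19 with doublets kept, 15 with at least 1000 UMIs, 17 with equal numbers of nuclei, 5 with scaling over all libraries, 14 with the 20% limit and 60 in set B alone. Committed oligodendrocyte precursor-like nuclei, also with 39, gave 7, 6, 17, 16, 13, 17 and 3 in the same order. List calls were 38 with sex as the only term, 0 with an estimated correlation and 1 in fry. D1 against D2 signalling genes fell from 53 to 31 in females only.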

Other observations

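Steroid receptor genes had their highest levels in different cell classes of the accumbens shell, though classes were shared and no test between classes was run. Drd3 MSN-like nuclei, first for Esr1, were also in the top 3 for Esr2 in 5 of 6 libraries. Esr1, the estrogen receptor alpha gene, was highest in Drd3 MSN-like nuclei, at 131 ± 48.7 CPM (SD, n = 6 libraries), where it ranked first among 14 classes in 6 of 6 libraries, with means of 72.4 in set A and 160 in set B. Astrocyte-like nuclei followed at 73.2 ± 17.3 CPM and cluster 9 at 71.1 ± 33.3, while oligodendrocyte-like nuclei had 14.7. Esr2, the estrogen receptor beta gene, was highest in oligodendrocyte-like nuclei at 42.2 ± 12 CPM, again first in 6 of 6 libraries, with 21.6 in Drd3 MSN-like, 4.04 in D1 MSN-like and 1.61 in OPC-like nuclei.

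The progesterone receptor gene Pgr stood at 40.8 ± 9.33 CPM in cluster 9 and at 33 ± 13.2 in Sst/Npy interneuron-like nuclei, against 6.03 in D2 MSN-like nuclei. Cyp19a1, the aromatase gene, had its highest mean in Sst/Npy interneuron-like nuclei at 15.5 ± 13.7 CPM from 34 counts, with libraries from 0 to 38.4 CPM.

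The tests of 1 library alone, glucocorticoid signalling, male pool 3 alone, an activity stimulus and doublets were chosen after seeing results, and the tests of MSN RNA, of the D1 and D2 mix and of other splits beforehand. Sgk1, higher in oligodendrocyte-like nuclei of females, has 3 explanations to weigh besides a sex difference, which stays open. RNA of medium spiny neurons would give 21.2% (SE 20.6) of the rise, which argues against it as the whole source, while a part stays open. Female pool 1, highest in Sgk1, had the lowest MSN marker RNA in these nuclei (2.52% of the D1 MSN-like level). A single library alone is argued against by the lowest log2 fold change of 1.40 when 1 library was left out. Glucocorticoid signalling that differed between the pools may contribute, since 4 of 8 other list members were higher in females in both sets, and this test cannot decide.

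Genes higher in females in cluster 19 could follow a different mix of D1 and D2 neurons. Of 32 called genes, 31 differed less between D1 and D2 MSN-like nuclei than between the sexes in cluster 19. The genes were chosen for a large sex difference, and D1 and D2 neurons were not compared within cluster 19. The values therefore argue only against a mix of nuclei like those of the D1 and D2 classes, and a mix within cluster 19 stays open. Male pool 3 alone is argued against as the only cause by a median log2 fold change of 0.96 without it, although the calls fell to 7. A stimulus of neuronal activity that differed between the pools may be part of it, since the immediate early list had a median above 0 in 4 of 5 MSN fits, counting Drd3 MSN-like nuclei, whose identity is uncertain. That test cannot separate a stimulus from a sex difference, and Nr4a3 and Homer1 lead the cluster.

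Genes higher in females in committed oligodendrocyte precursor-like nuclei may include RNA of medium spiny neurons, which would give 64.7% of the rise of the called genes. That value leans on female pool 2, whose 21 nuclei had MSN marker RNA at 50.7% of the D1 MSN-like level, against 8.52% and 18.1% in female pools 1 and 3 and a male mean of 8.89%, so the explanation stays open. Doublets stay open: with doublets kept and the nuclei clustered anew, 1 gene that is not sex-limited was called, and the log2 fold change of Gria1 in committed oligodendrocyte precursor-like nuclei was 1.47, against 2.67 without them. A sex difference was not tested apart from these.

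Other splits of the 6 libraries into 3 and 3 were compared with the split by sex, and 10 splits cannot give a share under 0.05. As many calls as by sex came in 2 of 10 splits in all nuclei (7 by sex, highest other 30), 2 in D1 MSN-like (7, 71), 2 in D2 MSN-like (8, 38), 1 in oligodendrocyte-like (8, 5), 1 in astrocyte-like (6, 1), 1 in eccentric MSN-like (7, 2), 1 in cluster 8 (8, 3), 1 in cluster 9 (8, 2), 1 in Drd3 MSN-like (7, 0), 3 in cluster 12 (7, 11), 3 in OPC-like (6, 10), 1 in cluster 19 (39, 2), 2 in Sst/Npy (7, 16), 1 in committed oligodendrocyte precursor-like (39, 0) and 2 in Pvalb/Pthlh nuclei (4, 7). For the interactions 10 of 10 had as many as the 0 by sex, with highest others of 32 for D1 against D2 MSN-like, 457 for D1 MSN-like against oligodendrocyte-like and 162 for D1 MSN-like against astrocyte-like nuclei. List tests gave 5 of 10 (59 by sex, highest other 75). Most of the highest counts came from female pool 1 with male pools 2 and 3. That split puts both set A libraries on the same side. In the fits with label set as a term it compares female pool 2 alone with the 3 other set B pools. The interaction fits had library as a block and no term for a class difference that varies with the label set. There the split sets both set A libraries and female pool 2 against the 3 other set B pools. These counts point to a structure of the samples. A split balanced over the label sets as the sex split is, female pools 1 and 3 with male pool 2, also called as many genes as sex or more in Sst/Npy (16), cluster 12 (9) and OPC-like nuclei (7), and 72 list tests. Another balanced split, female pool 1 with male pools 1 and 2, gave 60 list tests, and the remaining balanced splits gave 18, 50 and 21.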
